A study of Homo sapiens with 4 samples.

How the data were processed

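RNA from 4 samples of lipid-loaded Hep G2 cells was sequenced, per the labels, 2 libraries after transfection with the LysTTT-5'tRF mimic and 2 after a negative control. The labels' protocols give an RNA integrity number above 9.5 for every sample, 500 ng of total RNA as input, poly(A) selection, a stranded KAPA mRNA kit and a NextSeq 500 instrument. The deposited values were raw counts of reads per Ensembl gene in each library, with no normalization by the authors. Per the submitters' processing notes, FastQC, Bowtie2, STAR and HTSeq were used with the genome build GRCh38.p14; their versions, the annotation release and the strand setting of HTSeq are not given in the sources used here. A gene with an antisense or overlapping neighbour is therefore less certain than one without, and so are near-identical paralogs, since reads aligning to several places were left out of the gene counts.

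The table held 62655 gene IDs, of which 62590 could be given a symbol, and 5 HTSeq summary entries that name no gene. These entries were kept out of library sizes and tests. They held 23.1% of the total in each mimic library, 23.3% in control library 1 and 24.1% in control library 2. Reads counted to genes were 15430539, 18961222, 16793484 and 15970530 in mimic libraries 1 and 2 and control libraries 1 and 2. Both control columns carry the abbreviation that the series uses for its negative control. The other 2 columns carry a number that the labels do not explain and were taken as the mimic by elimination, since the series has 2 libraries per treatment and no other treatment. If that reading were wrong, the direction of the comparison would have no meaning. The columns were used as members of a group only. The numbers 1 and 2 are those of the columns; the sample titles number the controls 3 and 4, and the planned omission of samples 3 and 4 was carried out on control columns 1 and 2.

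Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries scaled with TMM factors, and the mimic compared with the control by the quasi-likelihood F test (glmQLFit with legacy = FALSE, then glmQLFTest), with Benjamini-Hochberg adjustment over the 14464 genes tested and a threshold of 0.05. The common biological coefficient of variation was 5.12%. The written design did not state the legacy option. It named legacy = TRUE as an alternative, which makes legacy = FALSE the primary setting, but a run with legacy = TRUE, one with DESeq2 and one with a block had been seen before this was settled; all are reported. CPM values are counts per 1000000 reads of the TMM-scaled library size, and group values are means ± SD of 2 libraries. With 2 libraries per group the residual degrees of freedom are few, and the test borrows the spread from genes of similar abundance.

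The comparison, the named-gene rule and 22 gene lists were fixed before the data were examined. The rule named KLB and PLIN2, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, up to 3 members with the smallest p from each called list, 1 from each other list, and the most abundant marker of another cell type; a gene that this rule names is not reported here. Lists with at least 5 tested genes were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Of 21 lists 5 were called with the preset value and 0 with either of the others. With an estimated correlation camera rests on the few residual degrees of freedom, so hardly any list could pass. The p53 targets had an estimated correlation of 0.00428, below the preset, yet their unadjusted camera p went from 0.0089 to 0.109. The other called lists had estimates above the preset of 0.01. These were 0.0625 for S phase, 0.155 for chaperones, 0.202 for hypoxia and glycolysis and 0.306 for immediate early genes. For those lists the preset p-values assume less shared movement between genes than was estimated. The adjusted p of 0.825 shared by the called lists came from the adjustment over lists and does not tell them apart. Members were also tested with p adjusted over the list alone.

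The edgeR and camera steps were tested on simulated data with the means and library sizes of these libraries. The simulated genes were independent of each other, with a spread set by abundance alone and no gradient within groups. Changes were planted only in genes with a mean of at least 5 CPM. The rates may therefore not carry over to the real libraries, which differ within groups. Among 14164 simulated genes, 43.3% of those changed 1.25-fold were called, 89.6% of those changed 1.5-fold and 97.0% of those changed 2-fold, with 13 false calls among 170. Changes of about 1.25-fold, close to the median size among the called genes, were thus often missed even in simulated data of this depth and number of libraries.

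The alternatives were DESeq2 1.42.0, limma voom, edgeR with legacy = TRUE, median-ratio, upper-quartile and library-total scaling, no filter on low counts, a filter at 10 CPM in 2 libraries, a test against a 1.2-fold change, other set tests, and the omission of each library in turn, in which the single library left in a group is assumed to vary like the other group. Added after seeing the data were a block on the column numbers, offsets for GC content and transcript length, and the unfiltered table with legacy = TRUE. Gene coordinates, overlaps, transcript lengths, GC content and 3' UTRs came from GENCODE release 29 on GRCh38, matched by gene ID. DESeq2 gave no adjusted p to 9 of the 50 called genes, and these were not counted as lost calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.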

Results

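The libraries came from Hep G2, an established human hepatocellular cell line that is widely used as a model of hepatocytes. Cells were plated at 150000 per ml, given medium rich in oleic acid 24 h later to load them with lipid, and transfected after another 24 h with either an oligonucleotide mimic of LysTTT-5'tRF or a negative control oligonucleotide. LysTTT-5'tRF is a fragment from the 5' end of the lysine tRNA with anticodon TTT. RNA was taken 24 h after transfection. The 4 poly(A)-selected libraries formed 2 groups of 2, mimic and control. Reads assigned to genes numbered 15430539 in mimic library 1, 18961222 in mimic library 2, 16793484 in control library 1 and 15970530 in control library 2. The labels call the libraries replicates without saying whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The comparison of mimic with control asked which transcripts differed when the fragment was added to lipid-loaded cells. The study's title names beta-Klotho and perilipin 2 (KLB and PLIN2) in connection with steatosis.

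KLB rose in cells given the mimic, and PLIN2 did not pass the test. KLB encodes beta-Klotho, the co-receptor through which FGF19 and FGF21 act on their receptors in liver and fat. Its expression was 212 ± 8.04 counts per 1000000 reads of the TMM-scaled library size (CPM) with the mimic and 155 ± 15.7 CPM in the control (mean ± SD, n = 2 each), a 1.37-fold rise. The log2 fold change was 0.45 with a standard error of 0.06 and a 95% interval from 0.33 to 0.58 (adjusted p = 0.000911, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The individual KLB values were 218 and 206 CPM with the mimic against 166 and 144 CPM in the control. PLIN2 encodes perilipin 2, a protein that coats lipid droplets. It stood at 1315 ± 49.8 CPM with the mimic and 1351 ± 44.7 CPM in the control (mean ± SD, n = 2 each). The PLIN2 log2 fold change of -0.04 had a 95% interval from -0.12 to 0.05 and an adjusted p of 0.845 (edgeR's quasi-likelihood test, Benjamini-Hochberg). A change of its mRNA was thus not detected with 2 libraries per group, and a log2 fall larger than 0.12 lay outside the interval. KLB (ENSG00000134962) lies on chromosome 4 from 39406853 to 39451536 and PLIN2 (ENSG00000147872) on chromosome 9 from 19108375 to 19149290 of GRCh38, both protein-coding and both free of exon overlap with other annotated genes. For this list of 2 genes, 1 rose both over all genes tested and when adjusted over the list alone (KLB adjusted p = 2.77e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The study may have picked both genes with these libraries, so the list is not independent evidence of a direction. KLB kept its call with each library left out, and lost it with no filter on low counts (adjusted p = 0.754, edgeR's quasi-likelihood test, Benjamini-Hochberg) and in a test against a 1.2-fold change (adjusted p = 1).

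**Figure D1:**
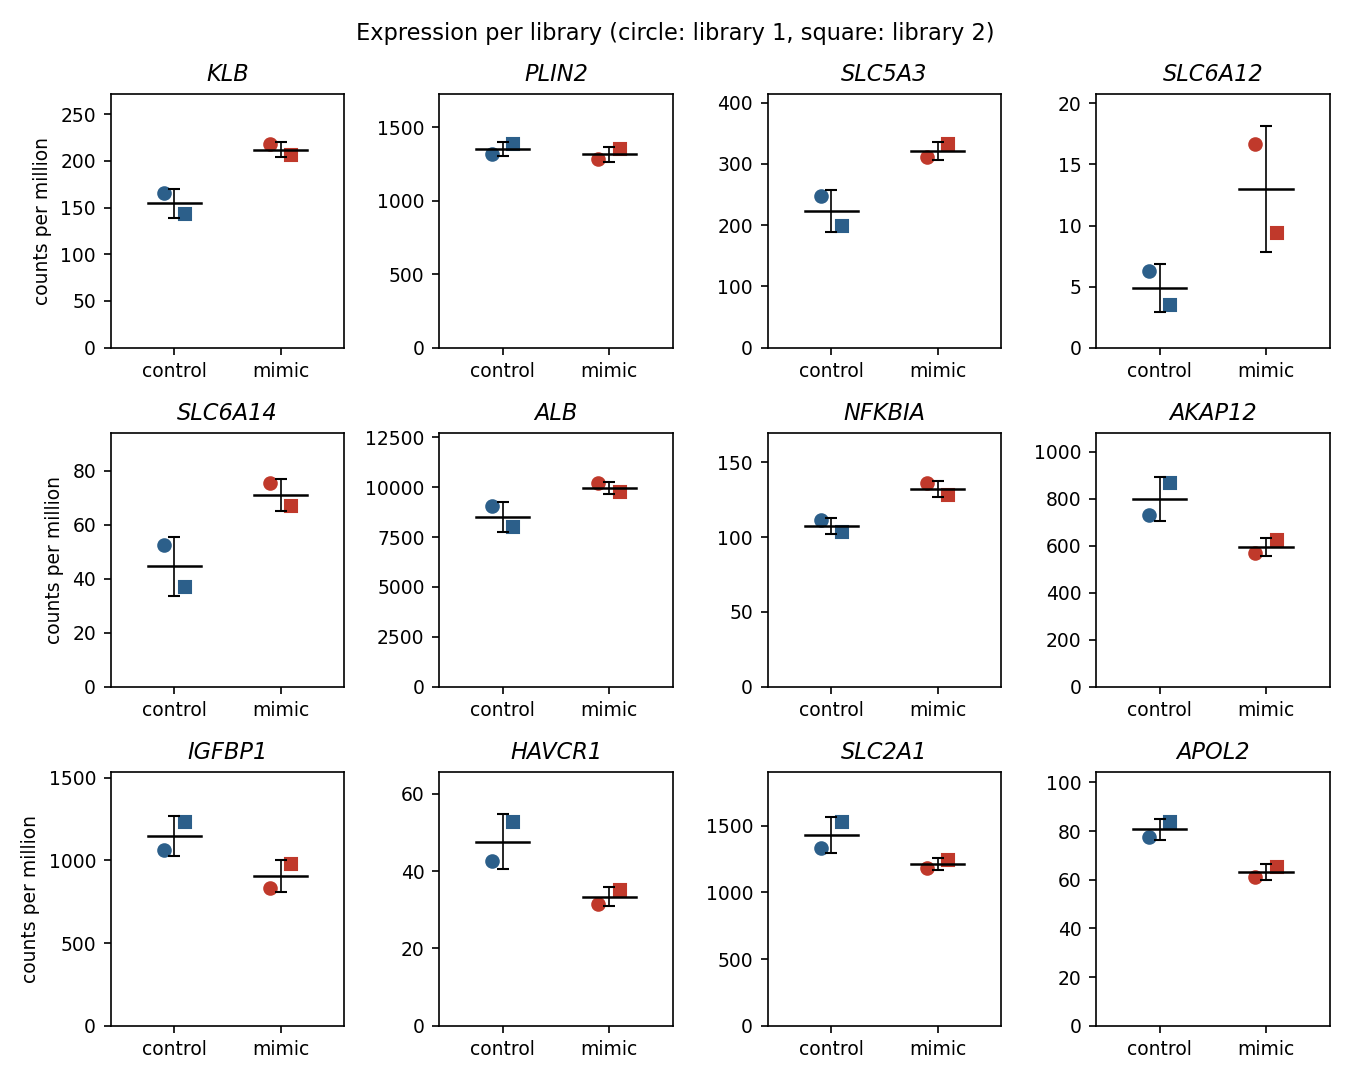
CPM in each library for 12 genes, with control in blue, mimic in red, library 1 as a circle and library 2 as a square. Horizontal bars are group means and error bars 1 SD (n = 2). KLB lies at 206 CPM or above in both mimic libraries and at 166 CPM or below in both controls, whereas the PLIN2 values of the groups overlap.

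Of 14464 genes tested, 50 differed between mimic and control at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 40 rose and 10 fell. The median size of the log2 fold change among these 50 was 0.34, and 4 of them (SLC6A12, HID1, SLC6A14 and PIK3AP1) changed by at least 1.5 times. At an unadjusted p under 0.05 there were 1364 genes, 732 higher and 632 lower with the mimic. The values of the groups did not overlap in any of the 50 genes, or in 39.1% of all tested genes, where chance gives 33.3% for 2 libraries against 2. The libraries also differed within groups along the direction of the comparison. In 48 of the 50 genes control library 2 lay farther from the mimic side than control library 1, and in 41 mimic library 1 lay farther from the control side than mimic library 2. The first principal component, with 40.7% of the variance, placed mimic library 1 at -23.0, mimic library 2 at -4.62, control library 1 at 1.53 and control library 2 at 26.0. The second, with 31.4%, did not separate the groups. It placed mimic library 1 at 16 and control library 2 at 13.7, but mimic library 2 at -9.26 and control library 1 at -20.5. Mimic library 2 and control library 1 had the highest pairwise correlation of log2 CPM, 0.9912. It was 0.9905 within the mimic and 0.9897 within the control. Leaving out 1 library changed the number of genes called to 20 without mimic library 1, 120 without mimic library 2, 424 without control library 1 and 22 without control library 2. With no filter on low counts edgeR called 0 genes, with 1514 at an unadjusted p under 0.05, while limma voom called 50, of which 47 were among the 50 above. DESeq2, which adjusted over 3133 genes, called 38, of which 28 were among the 50, and gave 9 of the 50 no adjusted p.

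**Figure D2:**
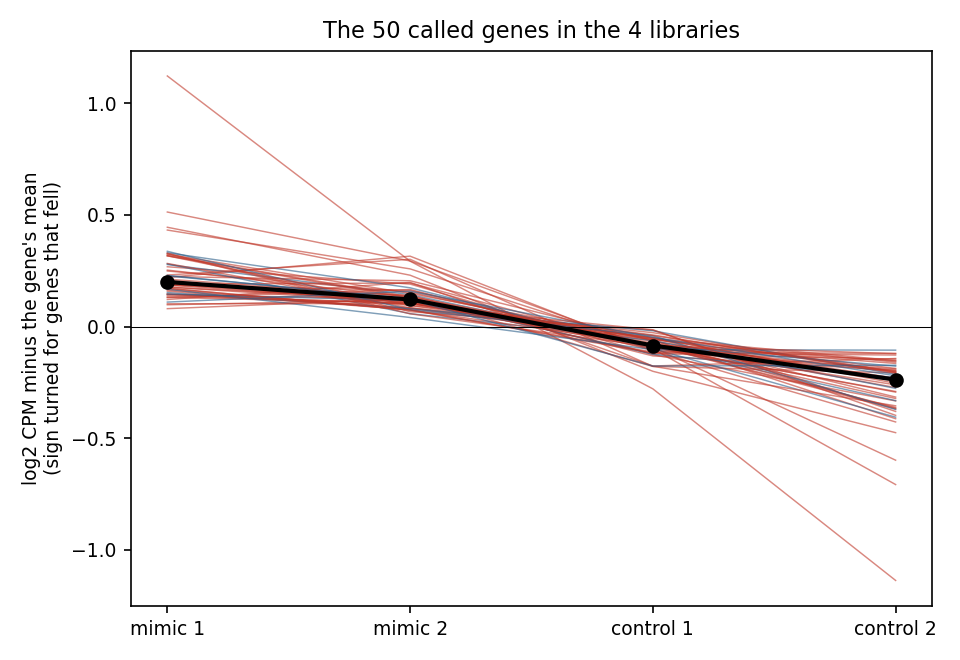
Log2 CPM of each of the 50 called genes minus its own mean over the 4 libraries, with the sign turned for genes that fell. Red lines are genes that rose, blue lines genes that fell, and the black line is the median, which was 0.20 and 0.12 in the mimic libraries and -0.08 and -0.24 in the controls.

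Of the 6 largest rises, 3 were of membrane carriers for osmolytes or amino acids. SLC6A12, which encodes the betaine and GABA transporter, rose 2.58-fold, from 4.89 ± 2.00 to 13.0 ± 5.15 CPM (mean ± SD, n = 2 each; log2 fold change 1.37, SE 0.25; adjusted p = 0.0121, edgeR's quasi-likelihood test, Benjamini-Hochberg). SLC5A3, the sodium-coupled myo-inositol transporter, rose 1.44-fold, from 223 ± 34.6 to 321 ± 14.9 CPM (log2 fold change 0.53, SE 0.07; adjusted p = 0.000911 by the same edgeR test with Benjamini-Hochberg adjustment). SLC6A14, a carrier of neutral and cationic amino acids, rose 1.58-fold, from 44.6 ± 10.96 to 71.1 ± 6.05 CPM. HID1, a protein of the trans-Golgi and secretory granules, rose by a log2 fold change of 0.76, the phosphoinositide 3-kinase adaptor PIK3AP1 by 0.66, and the secreted protein ODAM by 0.53. Of SLC5A3, 1.52% of the exon sequence is shared with MRPS6 and another gene on the same strand, and 1.55% of SLC6A12 lies opposite an antisense gene, so a small part of their counts is uncertain. The calls of SLC6A12, HID1 and PIK3AP1 were lost without mimic library 1 (log2 fold changes 0.93, 0.66 and 0.56), those of HID1, PIK3AP1 and ODAM without control library 2 (0.50, 0.53 and 0.45), and that of ODAM without mimic library 2 (0.49). SLC5A3 had an adjusted p of 0.0827 in DESeq2 (Wald test, Benjamini-Hochberg).

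The largest falls were modest. AKAP12, a scaffold that binds protein kinase A, fell from 799 ± 94.6 to 595 ± 39.3 CPM (mean ± SD, n = 2 each; log2 fold change -0.42, SE 0.06; adjusted p = 0.000911, edgeR's quasi-likelihood test, Benjamini-Hochberg). IGFBP1, the secreted insulin-like growth factor binding protein made by hepatocytes, fell from 1146 ± 120 to 906 ± 98.8 CPM (log2 fold change -0.34, SE 0.06; adjusted p = 0.00994 by edgeR with Benjamini-Hochberg adjustment). HAVCR1, also known as KIM-1, fell from 47.6 ± 7.13 to 33.4 ± 2.57 CPM, with a log2 fold change of -0.50. APOL2, of the apolipoprotein L family, and the cadherin CELSR3 each had a log2 fold change of -0.35, and the long intergenic non-coding RNA ENSG00000260604 on chromosome 6 had one of -0.41. The calls of HAVCR1, APOL2, CELSR3 and ENSG00000260604 were lost without mimic library 1 and without control library 2, where the log2 fold changes of HAVCR1 were -0.43 and -0.34 and those of APOL2 -0.30 and -0.29, those of CELSR3 -0.30 and -0.35, and those of ENSG00000260604 -0.29 and -0.23. CELSR3 passed in 6 of the 15 other settings that gave it an adjusted p, with log2 fold changes from -0.41 to -0.30, and ENSG00000260604 in 9 of 16, from -0.56 to -0.23, and DESeq2 gave adjusted p-values of 0.103 for AKAP12 and 0.439 for IGFBP1 (Wald test, Benjamini-Hochberg).

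The fixed lists of lipid genes held no called member other than KLB. Outside them the cholesteryl ester hydrolase NCEH1, named after its value was seen, rose by a log2 fold change of 0.35 (adjusted p = 0.0103, edgeR's quasi-likelihood test, Benjamini-Hochberg). None of the 22 tested genes for lipid droplets and lipolysis passed the test, nor of the 23 for fatty acid and triglyceride synthesis, the 24 for cholesterol synthesis and SREBP2 targets, the 27 for fatty acid oxidation and PPARA targets, or the 25 for lipid uptake and lipoprotein secretion. This held over all genes tested and when adjusted over the list alone. The median log2 fold changes of these lists lay between -0.06 and 0.00, and camera, with Benjamini-Hochberg adjustment over 21 lists, gave adjusted p-values of 0.645, 0.462, 0.544, 0.959 and 0.544 in the order given. The members with the smallest p were the lysophosphatidylcholine acyltransferase LPCAT1 (log2 fold change -0.20, 95% interval -0.34 to -0.06), the acyltransferase MOGAT2 (-0.41, -0.66 to -0.16), the sterol reductase TM7SF2 (-0.42, -0.72 to -0.12), the mitochondrial carnitine palmitoyltransferase CPT1A (0.19, 0.05 to 0.32) and the HDL receptor SCARB1 (-0.13, -0.24 to -0.02), none of which passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 17 tested genes for beta-Klotho, FGF receptors and bile acid metabolism, KLB alone rose, also when adjusted over the list alone, and 16 did not pass (median log2 fold change 0.03, camera adjusted p = 0.0892, Benjamini-Hochberg). That list was called without mimic library 1 (median 0.09, camera adjusted p = 0.0463, Benjamini-Hochberg) and without control library 1 (0.15, adjusted p = 0.0161), whereas without control library 2 its median was -0.02 (adjusted p = 0.857).

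Genes of hypoxia and glycolysis were lower with the mimic as a group. Of 27 tested members 20 lay below 0, with a median log2 fold change of -0.08 (camera adjusted p = 7.24e-05, Benjamini-Hochberg over 21 lists, and adjusted p = 0.825 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, fell from 1428 ± 136 to 1213 ± 42.8 CPM (mean ± SD, n = 2 each; log2 fold change -0.23, SE 0.05; adjusted p = 0.0319, edgeR's quasi-likelihood test, Benjamini-Hochberg). The other 26 members did not pass over all genes, among them the oxygen-sensing hydroxylase EGLN3 at -0.34 and the glycolytic regulator PFKFB4 at -0.23, and 6 members fell and 1 rose when adjusted over the list alone. The mean deviation of the list from the 4-library mean was -0.10 in mimic library 1, 0.01 in mimic library 2, 0.04 in control library 1 and 0.05 in control library 2. Without mimic library 1 the median was -0.04 and camera's adjusted p 0.168 (Benjamini-Hochberg). SLC2A1 lost its call without mimic library 1 (log2 fold change -0.20) and without control library 2 (-0.13), and had an adjusted p of 0.394 in DESeq2 (Wald test, Benjamini-Hochberg).

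**Figure D3:**
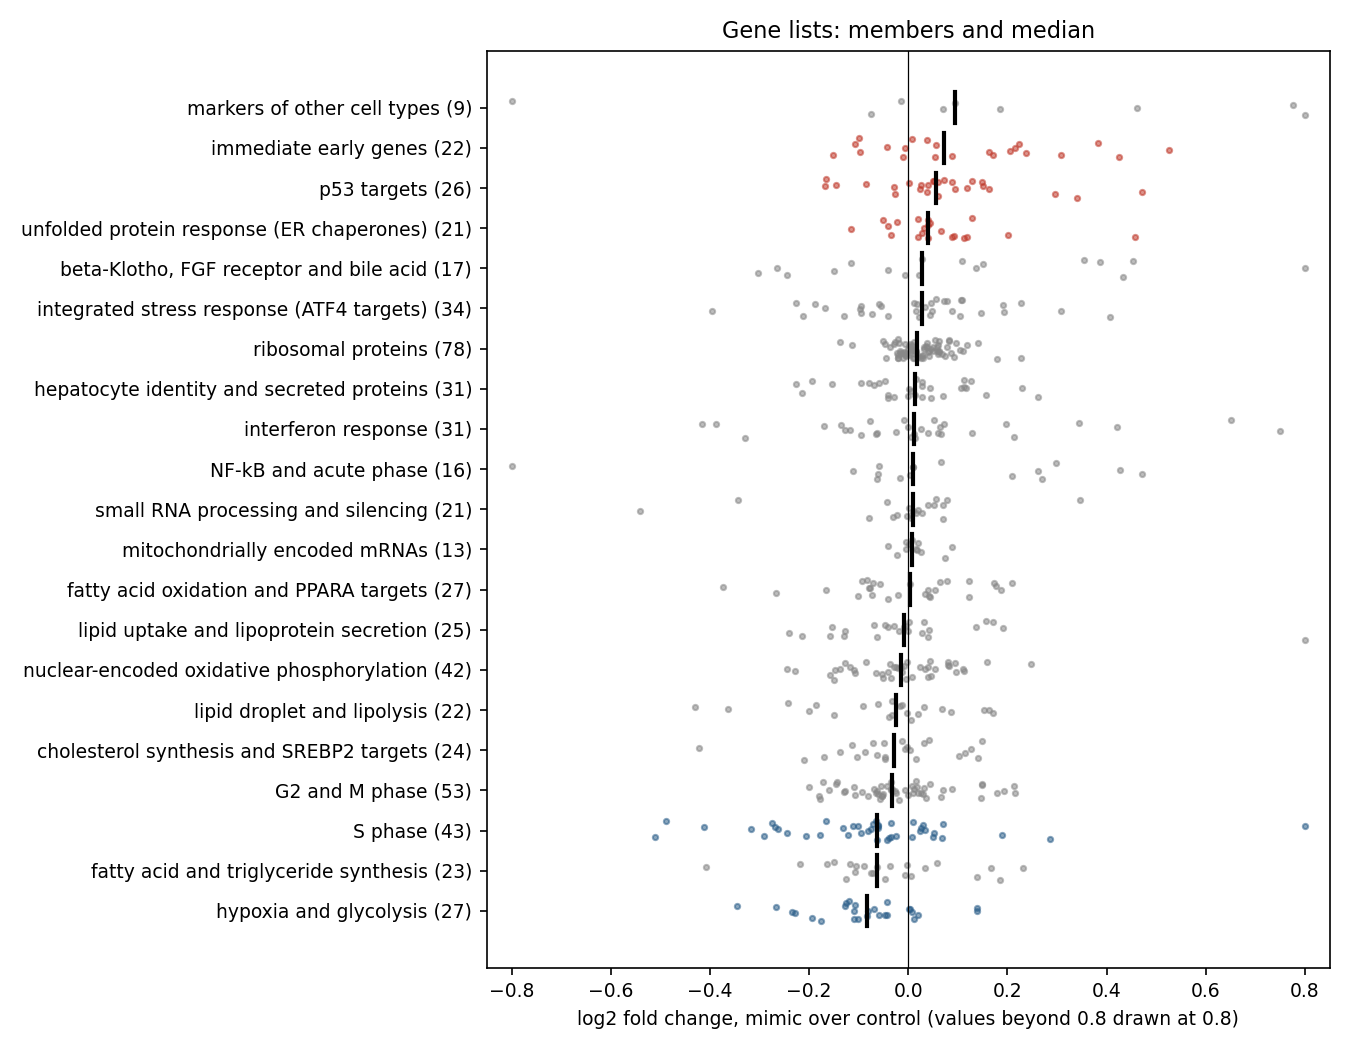
Log2 fold change, mimic over control, of every tested member of 21 gene lists, 1 point per gene, with the list median as a black bar and the number of tested members in brackets; points beyond 0.8 are drawn at 0.8. Lists called by camera with its preset correlation are red where higher and blue where lower, and the others are grey; with an estimated correlation 0 lists were called.

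Smaller shifts were called for 4 more lists, in which no member passed over all genes tested. Immediate early genes, transcription factors and feedback regulators induced within minutes of a stimulus, were higher with a median log2 fold change of 0.07 (camera adjusted p = 0.00654, Benjamini-Hochberg, and adjusted p = 0.825 with an estimated correlation). The groups overlapped in this list, since mimic library 2 lay below control library 1. Mean deviations from the mean of all libraries were 0.144 and -0.01 in mimic libraries 1 and 2. In control libraries 1 and 2 they were 0.046 and -0.18. When adjusted over the list alone 2 of its 22 members rose, JUNB with a log2 fold change of 0.43 and IER3 with 0.24, while ATF3 stood at 0.31 without passing. An antisense gene covers 26.5% of the IER3 exon sequence, and the strand setting of the counting is not given. S phase genes were lower, with a median of -0.06 (camera adjusted p = 0.013, Benjamini-Hochberg, and adjusted p = 0.825 with an estimated correlation), and of 43 members the replication helicase subunit MCM5 fell when adjusted over the list alone (-0.32), with CDCA7 at -0.29 and CDC45 at -0.51 not passing. Chaperones of the unfolded protein response were higher, with a median of 0.04 (camera adjusted p = 0.0272, Benjamini-Hochberg, and adjusted p = 0.825 with an estimated correlation). Of its 21 members HERPUD1 (0.20) and CRELD2 (0.46) rose when adjusted over the list alone, and CANX was at 0.09. The p53 targets were higher, with a median of 0.06 (camera adjusted p = 0.0374, Benjamini-Hochberg, and adjusted p = 0.825 with an estimated correlation), and of 26 members TP53INP1 (0.30) rose when adjusted over the list alone, while AEN at 0.15 and CDKN1A at 0.13 did not pass. Camera's calls, with Benjamini-Hochberg adjustment, were lost without mimic library 1 for immediate early genes (median 0.03, adjusted p = 0.45) and chaperones (0.01, adjusted p = 0.325), without mimic library 2 for S phase (-0.04, adjusted p = 0.322) and p53 targets (0.03, adjusted p = 0.333), without control library 1 for p53 targets (0.07, adjusted p = 0.172), and without control library 2 for immediate early genes (0.02, adjusted p = 0.813), S phase (-0.04, adjusted p = 0.434), chaperones (0.03, adjusted p = 0.719) and p53 targets (0.07, adjusted p = 0.0516). The chaperone and p53 calls were also lost with library totals (camera adjusted p = 0.076 for both, Benjamini-Hochberg), upper-quartile scaling (0.0555 for both) and a filter at 10 CPM (0.0892 and 0.165).

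Hepatocyte and inflammatory genes each held 1 called member. Albumin (ALB) rose from 8512 ± 737 to 9976 ± 306 CPM (mean ± SD, n = 2 each; log2 fold change 0.23, SE 0.04; adjusted p = 0.0109, edgeR's quasi-likelihood test, Benjamini-Hochberg), and of 31 hepatocyte genes 4 rose when adjusted over the list alone, ALB with TTR (0.26), APOH (0.16) and AFP (0.13), the last 3 named after their values were seen. That list as a whole was not called (median 0.01, camera adjusted p = 0.462, Benjamini-Hochberg). NFKBIA, the inhibitor that NF-kB itself induces, rose from 107 ± 5.43 to 132 ± 5.40 CPM (log2 fold change 0.30, SE 0.06; adjusted p = 0.0291, edgeR's quasi-likelihood test, Benjamini-Hochberg). Of 16 tested genes of NF-kB and the acute phase 15 did not pass, and 2 rose when adjusted over the list alone, NFKBIA and the chemokine CCL20 (0.27, named after its value was seen), with camera's Benjamini-Hochberg adjusted p at 0.104 (median 0.01). Without control library 1 that list was called higher (median 0.05, camera adjusted p = 0.0161, Benjamini-Hochberg). NFKBIA lost its call without mimic library 1 (log2 fold change 0.26) and without control library 2 (0.25), and ALB had an adjusted p of 0.329 in DESeq2 (Wald test, Benjamini-Hochberg) and of 0.054 in edgeR with a filter at 10 CPM.

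The remaining groups held no called gene. None of 31 interferon response genes passed, and IFIT1, with the smallest p, stood at 4.01 ± 0.329 CPM with the mimic and 2.38 ± 0.502 CPM in the control (mean ± SD, n = 2 each). The same held for 34 targets of ATF4 in the integrated stress response (PCK2, log2 fold change -0.21), 78 ribosomal proteins (RPS27, 0.14), 53 genes of G2 and M phase (ECT2, 0.18), 42 nuclear-encoded subunits of oxidative phosphorylation (CYC1, -0.23) and 13 mitochondrially encoded mRNAs (MT-ND3, 0.07). Camera's Benjamini-Hochberg adjusted p-values for these lists were 0.918 for interferon, 0.683 for ATF4 targets, 0.0673 for ribosomal proteins, 0.645 for G2 and M phase, 0.544 for oxidative phosphorylation and 0.645 for mitochondrial mRNAs. The ribosomal list, with a median log2 fold change of 0.02, was called higher without control library 1 (0.05, camera adjusted p = 0.000141, Benjamini-Hochberg) and turned lower without control library 2 (-0.00716, adjusted p = 0.88). Among 21 genes of small RNA processing and silencing (camera adjusted p = 0.79, Benjamini-Hochberg) none passed over all genes. The Argonaute genes AGO3 (log2 fold change 0.35) rose and AGO4 (-0.34, named after its value was seen) fell when adjusted over the list alone. Of 21 markers of stellate, endothelial and blood cells 9 were high enough to test and none passed (camera adjusted p = 0.413, Benjamini-Hochberg). The most abundant, LYZ, was at 1575 ± 63.9 CPM with the mimic and 1476 ± 2.52 CPM in the control (mean ± SD, n = 2 each), with 34.0% of its exon sequence opposite an antisense gene.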

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

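The block on column numbers, the GC and length offsets and the unfiltered table with legacy = TRUE were tests chosen only after the results were seen. All 50 called genes had the same sign in 15 of the 16 other settings, and in the 10 CPM filter 49 had it and 1 was not tested. The groups did not overlap in any of the 50, so leaving out 1 library could hardly turn a sign. The kept signs are therefore weak evidence. The number of calls (rises and falls) was 0 (0 and 0) with no filter on low counts and in the test against a 1.2-fold change, with 1514 and 283 genes at an unadjusted p under 0.05; DESeq2 called 38, 28 of them among the 50, and limma voom 50, 47 of them among the 50. The unfiltered table with legacy = TRUE called 135 (96 and 39), so the loss without a filter came with the dispersion method and not the filter alone. DESeq2 called 5 falls. Leaving out 1 library gave 20 to 424 calls, 16 to 276 rises and 4 to 148 falls, with 16, 44, 50 and 20 of the 50 genes called without mimic library 1, mimic library 2, control library 1 and control library 2. The labels' numbers pair no samples; the deviations of libraries that share a column number had a correlation of 0.0234 across 14464 genes, and the replicate block gave 306 calls (207 and 99). KLB had a log2 fold change of 0.45 with no filter (adjusted p = 0.754) and in the 1.2-fold test (adjusted p = 1), the 2 settings of 16 that ended its call (edgeR, Benjamini-Hochberg); its range was 0.36 to 0.56. PLIN2 was called in none. Called lists numbered 3 with library totals, upper-quartile scaling and the 10 CPM filter, each without chaperones and p53 targets, 8 with GC and length offsets, which added the beta-Klotho (adjusted p = 0.0232), ribosomal (0.000545) and NF-kB (0.0226) lists (camera, Benjamini-Hochberg), 0 with an estimated correlation and 0 with fry, and 1 to 7 with a library left out. The ribosomal list was also called with the replicate block (adjusted p = 0.0322) and by cameraPR (0.0424), which makes 4 of 14 settings, against 3 for the beta-Klotho list and 2 for the NF-kB list. Of 248 values of called named genes in other settings 182 kept their call and 66 lost it, and none changed sign with a call. Except for the filter, the cause was not tested.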

Other observations

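The tests on the gradient between libraries and on omission of single libraries from the NFAT5 and NRF2 targets, and that of mimic library 1 from the hypoxia list, were chosen only after the result was seen; the NFAT5 and NRF2 lists were chosen after the genes with the smallest p had been read, without taking genes seen there.

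The following called genes lie outside the named-gene rule and were picked after their values were seen, as single genes with no test of any group. The secreted protease inhibitors A2M (from 4177 ± 393 to 5120 ± 145 CPM, mean ± SD, n = 2 each; log2 fold change 0.29) and SERPINA5 (0.24) rose. The N-glycan branching enzymes MGAT5 (0.27) and MGAT4A (0.24) and the alanine transaminase GPT2 (0.22) rose. So did the collagen lysyl hydroxylase PLOD2 (0.30) and the zinc and iron carrier SLC39A14 (0.29). HIF1A, the oxygen-regulated transcription factor, rose by 0.24 while the hypoxia and glycolysis list was lower. The growth factor IGF2 fell (-0.21), although 75.0% of its exon sequence overlaps other annotated genes, INS-IGF2 among them.

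More of the called genes rose than fell, 40 against 10 (80.0% rises), but the size of this excess depended on single libraries: the share was 63.3% (76 and 44) without mimic library 2, 65.1% (276 and 148) without control library 1 and 80.0% (16 and 4) without mimic library 1. The lowest share of rises under 3 other scalings was 70.2%, and with offsets for GC content and transcript length it was 84.2%. These shares argue only weakly against scaling, GC content or length as the whole cause. Of the 57 genes called with offsets 43 were among the 50, as were 43 of 47 with library totals. Without control library 2 the share was 81.8%. Most of those calls were again among the 50, which kept their signs, so that test cannot decide on control library 2 alone. At an unadjusted p under 0.05 by edgeR's test, rises and falls were nearer to each other, 732 against 632. A gradient that also separates libraries of the same group remains open: control library 2 lay farther from the mimic side than control library 1 in 48 of the 50 genes. Control library 2 also had 10.4% of its total in reads aligned to several places, against 8.30% to 8.47% in the other libraries. With 2 libraries per group such a gradient and a response to the mimic of varying strength may both contribute to the calls.

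SLC5A3 and SLC6A12, carriers of the osmolytes inositol and betaine, rose, and both are known targets of the transcription factor NFAT5, which answers osmotic stress. All 10 other genes tested as NFAT5 targets lay above 0, including AKR1B1, PNPLA6 and the NFAT5 gene itself, but none was called. Their median log2 fold change was 0.14 (p = 8.36e-06 by limma's cameraPR, which sets a list against all other genes, n = 10 genes). The estimated correlation between these genes was 0.655, and with it the camera p was 0.236. The median was 0.0893 without control library 2, 0.0161 without mimic library 1, 0.205 without mimic library 2 and 0.192 without control library 1. Mean deviations of the list from the mean of all libraries were 0.203 in mimic library 1 and -0.0376 in mimic library 2. They were -0.012 in control library 1 and -0.153 in control library 2, so mimic library 2 lay below control library 1. Part of the shift remained without control library 2, but these genes move together and cannot decide on that library alone. Mimic library 1 alone may account for the shift of these targets. HSPA1A and HSPA1B are near-identical heat-shock genes that NFAT5 shares with other factors. MRPS6 shares part of the 1.52% of SLC5A3 exon sequence that overlaps other genes. Its log2 fold change was 0.247 (95% interval -0.02 to 0.51), too wide for the planned test on shared reads. However, MRPS6 stood at only 27.6 CPM with the mimic and 23.4 CPM in the control, against 321 and 223 CPM for SLC5A3. These levels and the small shared part argue against shared reads as the main source of the SLC5A3 rise. Higher NFAT5 activity is thus a hypothesis: the rise of SLC5A3 kept its call without mimic library 1 (log2 fold change 0.57), while the call of SLC6A12 (0.93) and the shift of the other targets were lost without it.

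The hypoxia and glycolysis list was lower with camera's preset correlation, and was not called with an estimated one (camera adjusted p = 0.825, Benjamini-Hochberg). Its median was -0.0839 in all libraries and -0.145 without mimic library 2. Control library 2 alone (median -0.0666 without it) and GC content or length (-0.0738 with offsets) were argued against as the whole cause. Without mimic library 1 the median was -0.0442. The mean deviation of the list was -0.10 in mimic library 1 and 0.01 in mimic library 2, against 0.04 and 0.05 in control libraries 1 and 2. Much of the shift thus came with mimic library 1, and whether any remains beyond that library stays open. The test on mimic library 1 was decided by camera's adjusted p and the test on control library 2 by the unadjusted one. By the unadjusted one the list would have passed without mimic library 1 as well. A difference in oxygen or glucose supply between wells could give such a shift and was not tested.

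A pair of further hypotheses stays open. AKR1C1 (log2 fold change 0.46) and AKR1C2 (0.40), paralogs whose reads are hard to separate, rose and are NRF2 targets, and 14 of 20 other NRF2 targets lay above 0 (median log2 fold change 0.04, cameraPR p = 0.155, n = 20 genes). The p depended on the libraries: it was 0.0112 without mimic library 2 (median 0.06) and 0.0119 without control library 1 (0.08), but 0.841 without mimic library 1 (-0.00306) and 0.88 without control library 2 (0.01), and it was 0.637 with an estimated correlation, so higher NRF2 activity is neither shown nor excluded. If the fragment acted like a microRNA through its bases 2 to 8, genes with a match in the 3' UTR would be lower; the mimic's sequence is not in the labels, and the site ATCCGGG was taken from the general sequence of this tRNA. Of 11929 genes with a 3' UTR, 216 held the site, with a median log2 fold change of -0.01 (cameraPR p = 0.758, n = 216 genes), and their mean statistic lay at the 25.2 percentile of 400 shuffled 7-mers. A fall of these genes was not detected, and small effects remain possible.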
